A study of Elaeis guineensis with 58 samples.

How the data were processed

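RNA from the spear leaf, the youngest unopened frond (F0), of oil palm (Elaeis guineensis) ortets was profiled by 3' end sequencing with a QuantSeq forward kit, per the labels' protocols. An ortet is the palm from which tissue is taken for cloning. The ortets came from 2 agencies, L1 and L2, and were grouped by past yield of embryoid lines into zero, low (1 to 89 lines) and high (at least 90 lines). The 58 libraries came from 52 palms. Replicates of a group were separate palms, and 6 L2 palms had a second library from a CTAB extraction in place of the InnuPREP kit.

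The values analysed were the authors' deposited read counts per gene, whole numbers with no normalization. Per the submitters' processing notes, bcl2fastq, STAR 2.7.2b and HTSeq 0.11.2 were used. The roles and settings of these tools, the strand setting and the genome build were not given in the sources used here. Each table held 27986 genes followed by 5 HTSeq summary lines, which were kept out of library sizes and tests. Reads with several alignments made up 23.4% ± 8.28 (SD, n = 32) of each L1 table, 14.1% ± 2.78 (SD, n = 20) of each L2 InnuPREP table and 24.9% ± 5.77 (SD, n = 6) of each CTAB table from L2. Reads outside any gene made up 18.0% ± 2.06, 9.83% ± 0.705 and 18.3% ± 1.75 of the same tables. Reads assigned to more than 1 gene made up 0.187% ± 0.0276, 0.595% ± 0.172 and 0.26% ± 0.0325. These shares are of all reads in a table, summary lines included. Counts of genes that share reads with a near-identical copy or an overlapping gene are therefore uncertain.

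Of the 27986 identifiers, 25047 were found by symbol in the EG11 gene table and 2939 were not. That table gives no product names for the 27805 LOC identifiers, so the 24 gene lists fixed by product name, cell type markers included, could not be matched and were not tested. In their place 9 lists of plastid genes were defined by symbol after the identifiers had been seen and before their values were tested. Of the named genes, 112 were plastid and 23 were nuclear. How well 3' end sequencing captures plastid transcripts, tRNAs among them, was not tested, so plastid values here are read counts only. EG11 was used only for names and for which genes neighbour each other.

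Each comparison was fitted with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filterByExpr filter, robust glmQLFit and glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05. Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM values were scaled by TMM, and log2 CPM used a prior count of 2. L2 high palms were compared with zero and low palms together, and L1 low palms with zero palms, as the series' design text sets out. The 3 L2 groups were also compared pairwise in 1 fit. CTAB and InnuPREP libraries were compared with the palm as a block, since the palm label pairs them. Deviations from the method means correlated at 0.62 to 0.76 between the paired libraries of a palm and at most at 0.22 between palms. No 2 of the 58 libraries held identical values. Plastid lists of at least 5 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, in limma 3.58.1. Library measures were compared by permutation tests in scipy 1.17.1, exact where a group held fewer than 10 palms and otherwise with 100000 resamples, all two-sided.

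The groups, tests and alternatives listed for each comparison were fixed before the data were examined, except those said to be chosen afterwards. The alternatives were RLE scaling, DESeq2 1.42.0, limma-voom with quality weights, other filters on low counts, a 2-fold minimum, genotype as a term, embryoid lines as a continuous term and counts thinned to the smallest library. Leaving out single palms, terms for library quality (shares of multi-mapped and plastid reads and log total, and in L2 shares of reads outside genes and of the 10 most abundant genes) and a term for the palm identifier were among those added after the data had been seen. Named genes were to be taken by fold change among called genes with a product name and a mean log2 CPM of at least 1. Without product names, at most 2 LOC identifiers that rose and 2 that fell by the largest fold change were named per comparison. All nuclear genes with a symbol and up to 3 called genes per plastid list were named as well, a choice made after the identifiers were seen. Where no gene was called, the 2 LOC identifiers of smallest p were named.

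Total counts in genes ran from 3943437 to 9685451 in L1, from 8773354 to 15004694 in L2 InnuPREP libraries and from 4215872 to 7580573 in L2 CTAB libraries. The fits were tested on simulated counts drawn independently for each gene and library from the real means and dispersions, with 200 genes changed. For L2 high against zero-low, edgeR recovered 57% of 2-fold and 92% of 4-fold changes among 19843 genes, with 6 false calls. For L1 low against zero, it recovered 74% and 93% among 18275 genes, with 7 false calls. For L2 low against zero, it recovered 26% and 87% among 20201 genes, with 5 false calls. For CTAB against InnuPREP, it recovered 80% and 96% among 20582 genes, with 20 false calls. For the L1 genotype comparison, it recovered 49% and 85% among 19148 genes, with 1 false call. DESeq2 gave 27 false calls for L2 high against zero-low and 29 for L1 low against zero, and limma-voom 7 in each. The labels name no molecular identifiers, so intervals on counts cover counting error only.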

Results

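Spear leaf transcriptomes were compared between oil palm ortets that had yielded no, few or many embryoid lines. Agency L1 supplied 17 zero and 15 low palms, the latter with 10.2 ± 15.8 lines (SD, n = 15) and a median of 2. Agency L2 supplied 6 zero palms, 6 low palms with 25.2 ± 14.9 lines (SD, n = 6) and 8 high palms with 247 ± 159 lines (SD, n = 8). The medians of these low and high palms were 32.5 and 185 lines. L1 libraries were made from CTAB extracts and L2 libraries from InnuPREP extracts, with a second CTAB library for 6 L2 palms. Total gene counts per library were 6292203 ± 1449999 in L1 (SD, n = 32), 12095610 ± 1615633 in L2 InnuPREP libraries (SD, n = 20) and 5934010 ± 1084737 in L2 CTAB libraries (SD, n = 6). Genotype labels followed the groups in L2. All 6 zero palms and no others were Yangambi_A. The low palms were 4 Yangambi_B, 1 Yangambi_C and 1 Jen Avros. The high palms were 6 Jen Avros, 1 Yangambi_C and 1 Jen Avros Yangambi.

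The leaf transcriptome of L2 palms with high embryogenesis differed from that of zero and low palms in 8113 of 20008 genes, 4055 higher and 4058 lower. At least 2-fold changes were found in 1349 higher and 1766 lower genes. LOC105058870 fell from 111 ± 63.6 CPM (SD, n = 12) in zero-low palms to 3.27 ± 3.27 CPM (SD, n = 8) in high palms, a log2 fold change of -5.07 ± 0.57 (SE), with an adjusted p of 6.34e-06 by edgeR. LOC105054824 fell from 5.51 ± 6.58 to 0.133 ± 0.179 CPM, with 0.53 to 20.5 CPM in zero palms and 0.103 to 3.38 CPM in low palms, of which low palms 4 and 5 lay below high palm 8 at 0.493 CPM. LOC105052784 rose from 5.03 ± 5.97 to 212 ± 391 CPM, and LOC105044093 from 1.79 ± 2.15 to 52.3 ± 82.8 CPM. In both of these genes 1 high palm lay far above the rest and raised the mean. For LOC105052784 it was high palm 1, at 1170 CPM against 3.7 to 218 CPM in the other high palms. For LOC105044093 it was high palm 5, at 247 CPM against 0.247 to 74 CPM. High palm 8, at 3.7 CPM, lay below the highest low palm, at 20.7 CPM, for LOC105052784, and high palms 3, 7 and 8, at 4.4, 3.46 and 0.247 CPM, lay below the highest zero palms, at 5.56 CPM, for LOC105044093. The 4 calls held without each palm in turn, in 20 fits each, except that LOC105054824 passed the count filter in only 12 of them.

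Of the 13 nuclear genes with a symbol that were tested, 6 were called over all genes and 7 when adjusted over the list alone. GPAT, a glycerol-3-phosphate acyltransferase, fell from 26.4 ± 6.8 CPM (SD, n = 12) to 11.3 ± 4.61 CPM (SD, n = 8), with an edgeR adjusted p of 0.000133. IAA1, an Aux/IAA gene of auxin signalling, fell from 189 ± 60.3 to 81.2 ± 56.7 CPM, with an edgeR adjusted p of 0.00472. GST, a glutathione S-transferase, fell by 0.82 ± 0.32 (SE) on the log2 scale. GSK rose by 0.88 ± 0.22, DRM by 1.13 ± 0.41 and GLO2 by 0.73 ± 0.25 on the log2 scale (SE). Set against the mean log2 CPM of zero-low palms, high palms lay on the side of the change in 8 of 8 palms for GPAT. They did so in 7 of 8 for IAA1 and GSK, and in 6 of 8 for GST, DRM and GLO2. The log2 differences of the genes not called over all genes were 0.45 for AHP1, the gene called when adjusted over the list alone, -0.38 for PTE, -0.2 for CPRZ, 0.19 for ADPRF and HCS, -0.06 for CPRF and 0.03 for TCTP, a translationally controlled tumour protein. Leaving out 1 palm ended the call of GST in 12 of 20 fits, of GLO2 in 4 and of DRM in 3. The call of GST ended without high palm 2, 3, 4, 6 or 8, zero palm 2, 3, 4 or 6, or low palm 1, 4 or 5, that of GLO2 without high palm 2, 3, 5 or 6, and that of DRM without high palm 1, 2 or 5. Library quality terms, for multi-mapped share, plastid share and log total, ended the calls of DRM, GLO2 and GST, and the use of CTAB libraries for 6 palms those of GLO2 and GSK.

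Of 84 plastid genes tested in L2, 4 were higher and 6 lower in high palms, and 2 were called when adjusted over the list alone. These are read counts from 3' end libraries, whose capture of plastid transcripts was not tested. The glutamate tRNA gene trnE-UUC fell from 103 ± 34.7 CPM (SD, n = 12) to 30.2 ± 8.03 CPM (SD, n = 8), with an edgeR adjusted p of 8.1e-06. The tyrosine tRNA gene trnY-GUA fell from 101 ± 24.6 to 48 ± 22 CPM, with an edgeR adjusted p of 0.00119. The photosystem genes psaJ and psbA rose by 0.76 ± 0.24 and 1.01 ± 0.34 on the log2 scale (SE), and psbJ fell by 0.8 ± 0.24. High palms lay on the side of the change from the zero-low mean log2 CPM in 8 of 8 palms for psaJ, 7 of 8 for psbJ and only 5 of 8 for psbA. The call of psbA was lost without high palm 2 or 7, with library quality terms, with limma-voom and with CTAB libraries for 6 palms, and the last also ended that of psaJ. The other called genes were ndhD at 0.4, trnS-GCU at 0.63, petD at -0.58, ndhA at -0.61 and rpl36 at -0.61 on the log2 scale. The call of trnS-GCU ended with limma-voom and without high palm 1, 2, 4, 5 or 6, zero palm 1, 2 or 4, or low palm 1, 2, 4, 5 or 6. That of petD ended without high palm 1, 2, 3, 5 or 7, zero palm 3 or 4, or low palm 6. That of ndhD ended without high palm 1, 2 or 3, zero palm 1 or 5, or low palm 5, with thinned counts, with quality terms and with CTAB libraries, which also ended that of rpl36. No plastid list passed camera, with an adjusted p of 0.905 for all plastid genes, or 0.957 with an estimated correlation. In fry's test for change in either direction, the plastid tRNA list had an adjusted p of 2.34e-05. The plastid share of counts was 3.05% ± 0.847 in high palms (SD, n = 8) and 3.08% ± 0.748 in zero-low palms (SD, n = 12), with an adjusted p of 0.985 in an exact permutation test. The 10 most abundant genes took 10.8% ± 1.99 of counts in high palms and 8.24% ± 1.18 in zero-low palms, with an adjusted p of 0.018 in the same exact test over 5 measures. Reads outside any gene made up 9.35% ± 0.507 in high and 10.1% ± 0.651 in zero-low palms, with an adjusted p of 0.0242 in that exact test.

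Genotype could be separated from embryogenesis only in part in these L2 palms, Jen Avros and Yangambi_C being the labels that hold both high and low palms. No zero palm carries either label. Every high palm of these labels has an identifier beginning with U and neither low palm does. A fit with genotype as a term thus cannot separate the group from the identifier series. With genotype as a term, 1241 genes were called, and LOC105054824, LOC105058870, GPAT, trnE-UUC and trnY-GUA were the 5 of 20 named genes that kept their call. The other 15 kept their direction, with log2 differences such as 1.19 for GSK, -1.09 for IAA1 and 0.22 for GLO2. With the first letter of the palm identifier as a term, chosen after seeing the data since 7 of 8 high palms have identifiers beginning with U, 1 gene was called. With the share of reads outside genes and that of the 10 most abundant genes as terms, also chosen after seeing the data, 1109 genes were called. The second share is computed from the gene counts, so it can take out part of a difference in expression. LOC105054824, LOC105058870, GPAT, GSK, GST and trnE-UUC were the 6 of 20 named genes that kept their call in that fit, and the log2 differences of DRM and trnS-GCU turned to -0.37 and -0.12.

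Each palm was placed on the axis from the zero-low mean at 0 to the high mean at 1, using means computed without it. High palms scored 0.92 ± 0.21 (SD, n = 8), low palms 0.14 ± 0.28 (SD, n = 6) and zero palms -0.05 ± 0.1 (SD, n = 6). The low Jen Avros palm scored -0.04, whereas the 6 high palms of that genotype label scored 0.8 to 1.1. The low Yangambi_C palm scored 0.66 and the high Yangambi_C palm 0.97. The high Jen Avros Yangambi palm scored 0.47. Within high palms the score and the log2 number of embryoid lines gave a Pearson r of -0.0787 (exact permutation p = 0.8, n = 8) and a Spearman rho of -0.357 (exact permutation p = 0.389). Within low palms r was 0.109 (exact permutation p = 0.944, n = 6) and rho 0.371 (exact permutation p = 0.497). All 4 adjusted p were 0.944, and r was -0.51 and 0.49 without the 2 palms farthest from the median number of lines.

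**Figure D1:**
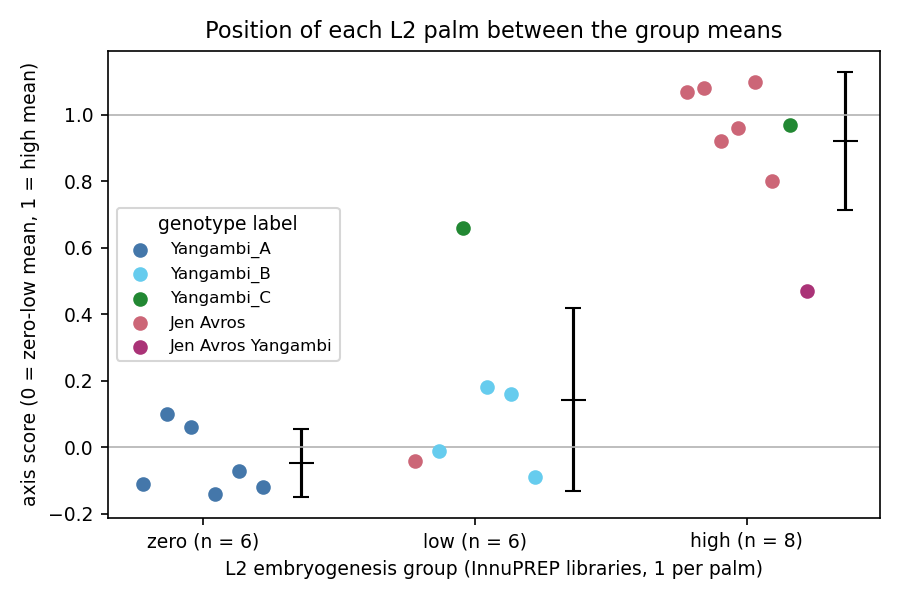
Axis score of each L2 palm (vertical, no unit) by embryogenesis group (horizontal), with points coloured by genotype label and bars giving mean and SD. High palms sit between 0.47 and 1.1 and zero palms between -0.14 and 0.1, with 1 low palm at 0.66.

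**Figure D2:**
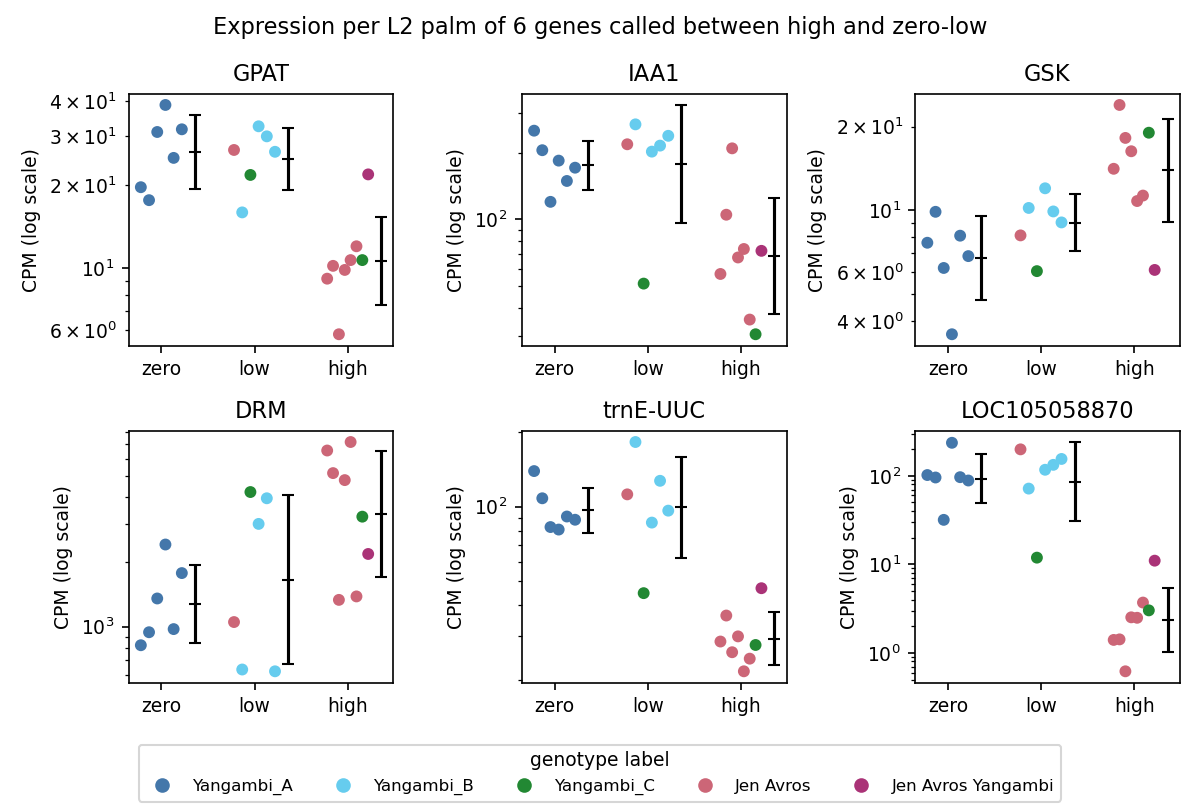
Expression of 6 genes in CPM (vertical, log scale) in each L2 palm by group (horizontal), with points coloured by genotype label and bars giving the mean and SD of log2 CPM. GPAT, IAA1, trnE-UUC and LOC105058870 are lower and GSK and DRM higher in most high palms.

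Split by reference group, high palms differed from zero palms in 7330 of 20413 genes, 3745 higher and 3585 lower (edgeR). They differed from low palms in 5740, 2655 higher and 3085 lower (edgeR). Every zero palm and no high palm was Yangambi_A, so group and genotype cannot be told apart in high against zero. LOC105061162 was nearly absent from zero palms, with 1 count over 6 libraries, against 1131 counts over 8 high libraries. That is a ratio of 792 with an exact 95% counting interval of 142 to 31300. LOC105036497 rose from 0.616 ± 0.703 CPM (SD, n = 6) in zero to 82.9 ± 98.9 CPM (SD, n = 8) in high palms, though 3 counts in high palm 3 and 10 in high palm 8 lay within the 0 to 24 counts of zero palms. LOC105035002 had 2 counts over the 8 high libraries and 522 over the 6 zero libraries, a ratio of 373 with an interval of 103 to 3080. DRM rose by 1.53 ± 0.5 and GSK by 1.08 ± 0.26 from zero to high palms (SE), while GPAT fell by 1.27 ± 0.24 and IAA1 by 1.15 ± 0.37 on the log2 scale. These were the 4 of 13 nuclear genes with a symbol called, also 4 when adjusted over the list alone. From low to high palms GPAT fell by 1.17 ± 0.24, IAA1 fell by 1.29 ± 0.37 and GSK rose by 0.7 ± 0.26 (SE), the 3 of 13 called, or 2 when adjusted over the list alone. Plastid trnE-UUC fell by 1.7 ± 0.23 against zero palms and fell by 1.84 ± 0.24 against low palms, among 7 and 5 of 85 plastid genes called, or 1 and 2 when adjusted over the list alone.

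Low and zero L2 palms differed in 36 of 20413 genes by edgeR, 16 higher and 20 lower in low palms. Every zero palm and no low palm was Yangambi_A, so these genes cannot be assigned to group rather than genotype. LOC105061162 had 1026 counts over the 6 low libraries against 1 over the 6 zero libraries, a ratio of 1050 with an interval of 188 to 41400, and the low Yangambi_C palm had 0. LOC105036497 rose from 0.616 ± 0.703 to 86.7 ± 59.5 CPM (SD, n = 6 each). LOC105037778 fell from 14.5 ± 3.49 CPM (SD, n = 6) in zero palms to 1.63 ± 1 CPM (SD, n = 6) in low palms, and LOC105048405 from 17.3 ± 4.7 to 2.52 ± 2.64 CPM. No nuclear gene with a symbol and no plastid gene was called, of 13 and 85 tested, with 0 in each when adjusted over the list alone. Over all genes, 2464 had an unadjusted p below 0.05 by edgeR, DESeq2 called 328 genes, and edgeR with no filter on low counts called 16. The count moved to 147 without zero palm 2 and 106 without low palm 2, and to 7, 5, 9, 3 and 8 without zero palms 1, 3, 4, 5 and 6, and 6, 5 and 4 without low palms 1, 4 and 5.

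In L1, no gene was called between low and zero palms among 18434 tested by edgeR, by DESeq2 or by limma-voom. By edgeR, 1337 genes had an unadjusted p below 0.05, against 922 expected, and the smallest adjusted p was 0.434. The 2 LOC identifiers of smallest p, neither past the threshold, were LOC105056307 at 1.6 ± 0.988 CPM in low (SD, n = 15) and 4.69 ± 2.87 CPM in zero palms (SD, n = 17), and LOC105045692 at 53.4 ± 152 and 3.31 ± 5.49 CPM. Among nuclear genes with a symbol, 0 of 15 were called, also when adjusted over the list alone. GPAT stood at 27.7 ± 9.74 CPM in low and 30.9 ± 5.88 CPM in zero palms, and IAA1 at 54.8 ± 28.8 and 42.8 ± 27.8 CPM. Of 19 genes named as called in L2 and tested in L1, 12 had the same sign in L1 and 0 passed the threshold. Leaving out low palm 9 gave 1 called gene. Within each of the Dumpy Avros and Dumpy Yangambi Avros labels alone, 0 genes were called by edgeR.

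Plastid genes in L1 had a median log2 difference of -0.12 between low and zero palms, with 0 of 83 called. Camera at its preset correlation gave lower values in low palms for all plastid genes together (6.94e-06) and for 4 of 8 lists, photosystem I (0.0204), photosystem II (0.000574), ribosomal proteins (0.0204) and tRNA (0.00758), with adjusted p in brackets. All plastid genes and each of the 8 lists had an adjusted p = 0.6 with an estimated correlation, and fry called none. The NDH list had a median of 0.04 and a mean of -0.12. The plastid share of counts was 10.7% ± 3.51 in low (SD, n = 15) and 12.1% ± 2.5 in zero palms (SD, n = 17), with an adjusted p of 0.603 in a permutation test.

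Dumpy Avros and Dumpy Yangambi Avros palms of L1 differed in 0 of 19272 genes by edgeR, with 1396 at an unadjusted p below 0.05 and a smallest adjusted p of 0.16. DESeq2 called 21. LOC105033495, not past the threshold, stood at 0.417 ± 0.303 CPM in Dumpy Avros (SD, n = 12) and 9.58 ± 19.2 CPM in Dumpy Yangambi Avros palms (SD, n = 20). LOC105050513, also not past it, stood at 37 ± 26.8 and 13.1 ± 6.41 CPM.

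Fold changes of low over zero palms in L1 were close to unrelated across genes to those of L2. Pearson's r was 0.048 against L2 high over zero-low and -0.089 against L2 low over zero. These values are over 18071 and 18160 genes. Other groupings of the L1 palms gave -0.343 to 0.36 and -0.202 to 0.198. Genes are not independent replicates, and 81 and 51 of 100 groupings lay as far from 0. As no gene was called in L1, an r near 0 cannot tell whether the agencies share a response. The low minus zero difference itself differed between agencies in 10 of 20616 genes by edgeR. Among those genes with a mean log2 CPM of at least 1, LOC105061162 and LOC105036497 had the largest positive values. LOC105060146 and LOC105052074 had the largest negative values. In L2 every zero palm and no low palm was Yangambi_A, so an agency difference in embryogenesis cannot be told apart from genotype. The count of genes called moved to 27 without zero palm 2, 19 without low palm 6, and 3 without zero palm 3, 5 or 6 or low palm 2. It moved to 4 without zero palm 1 or low palm 4 or 5, and 6 without low palm 3. All of these are L2 palms, and no L1 palm was left out of this fit.

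The 6 palms extracted by both methods gave CTAB and InnuPREP libraries that differed in 11198 of 20803 genes, 5262 higher and 5936 lower in CTAB libraries (edgeR, paired by palm). Without the palm as a block, 2875 genes were called. Plastid genes were mostly higher in CTAB libraries, with 59 of 88 higher and 3 lower, and 63 called when adjusted over the list alone. The plastid ribosomal protein genes rps14 and rps3 rose by 3.06 ± 0.11 and 1.97 ± 0.08 on the log2 scale (SE), and 12 of 17 genes of that list rose. All 9 genes of the list of other plastid proteins rose, among them infA, ccsA and ycf3. Photosystem I gene psaC rose from 8.34 ± 2.89 to 50.7 ± 18.9 CPM (SD, n = 6). Camera called 6 of 8 lists at its preset correlation and none with an estimated correlation, where ribosomal proteins and other proteins had an adjusted p of 0.0524 and the others 0.108 to 0.263. Fry called all 8. The plastid share of counts was 6.24% ± 1.2 in CTAB and 3.12% ± 0.801 in InnuPREP libraries (SD, n = 6), higher in 6 of 6 palms, with an adjusted p of 0.0312 in an exact sign permutation test, the smallest it can give.

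Of 15 nuclear genes with a symbol, 10 were called between the methods, 2 higher and 8 lower in CTAB libraries, and 10 when adjusted over the list alone. GSK rose by 1.64 ± 0.2 and GPAT by 0.51 ± 0.1 on the log2 scale (SE). PTE fell by 1.03 ± 0.1, DRM by 0.88 ± 0.09, AHP1 by 0.8 ± 0.1, GST by 0.78 ± 0.09, HCS by 0.77 ± 0.12, ADPRF by 0.64 ± 0.09, IAA1 by 0.47 ± 0.09 and TCTP by 0.3 ± 0.09 on the log2 scale (SE). LOC105057176 rose from 134 ± 42.5 to 1850 ± 713 CPM and LOC105037779 from 0.683 ± 0.534 to 13.5 ± 10.7 CPM (SD, n = 6). LOC105051136 fell from 554 ± 144 to 38.7 ± 6.72 CPM and LOC105054994 from 5.32 ± 5.78 to 0.227 ± 0.211 CPM. Total counts were 5934010 ± 1084737 in CTAB and 12657736 ± 2153645 in InnuPREP libraries (SD, n = 6), so depth differed along with the method.

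**Figure D3:**
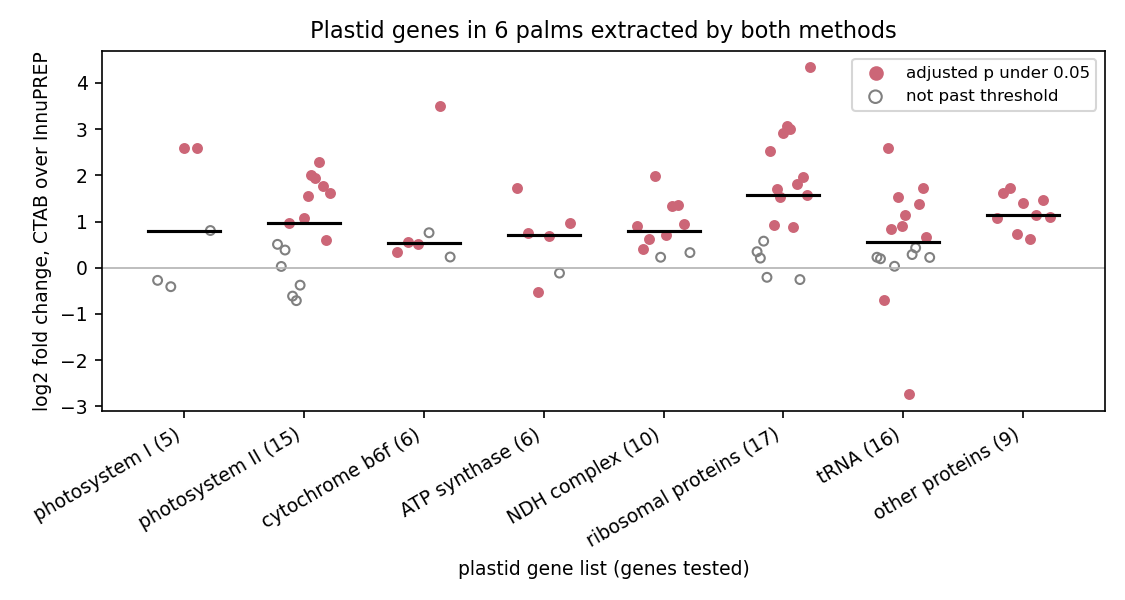
Log2 fold change of CTAB over InnuPREP libraries (vertical) for each tested plastid gene by list (horizontal, number of genes in brackets), in 6 palms extracted both ways, with black lines for medians. Filled points passed the threshold, 59 of 88 plastid genes higher and 3 lower.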

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

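The tests of the palm identifier, of the spread in L1, of reads assigned to more than 1 gene, of library quality terms, of reads outside genes with the 10 most abundant genes, and of thinned CTAB counts were chosen only after the data had been seen. Of 79 groups of 4 to 10 values tested for 1 value apart from the rest, 13 had one, against about 4 by chance (5% of groups). The 5% assumes independent groups of normally distributed values. These groups reuse the same palms and most hold CPM, not on the log scale, of genes picked as called. The excess over 4 therefore decides nothing.

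The high against zero-low difference in L2, 8113 genes, was reached by 1 of 100 splits of the 20 palms, the real one, with 1259 genes in the highest other. A chance draw of single palms is thus unlikely to give it. The splits took no account of genotype or identifier series. They cannot exclude a block of palms sharing either that coincides with the high group. Genes called in 14 palms correlated at 0.831 with the CTAB fold changes of the other 6 palms, which argues against an effect of the InnuPREP libraries alone. Library quality stays open. Multi-mapped share, plastid share and log total left 7745 genes called but account for 12.4% of the variation in group and so decide nothing. Reads outside genes and the share of the 10 most abundant genes account for 59.7% and left 1109, between the bounds set. The latter share is computed from the gene counts themselves, so that drop cannot tell library quality from a difference in expression. Genotype (1241 genes called with it as a term, between the bounds set) and the palm identifier series (0.47 for the only high palm outside it, about midway between the groups) stay open too. The embryogenesis group, the biological explanation in the design, overlaps with all of these in most palms and stays open with them.

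The count of 0 genes between low and zero palms in L1 (edgeR; 1337 at an unadjusted p below 0.05, 0 by DESeq2 and limma-voom) is the least any split can give, so the 100 of 100 splits that reached it, with 1 in the highest other, decide nothing. Terms for multi-mapped share, plastid share and log total left 0 genes called. By the bound on genes called set before that count was known, this would have counted against library quality. The residual SD with these terms was 0.964 of that without, at or above 0.95, so they moved too little to decide and quality stays open. The 0.95 was set after the 0 genes were known and before the ratio was computed. A wider spread between L1 palms stays open too, since the residual SD was 1.285 times that in L2, above the bound of 1.2, but 1.09 times with all libraries thinned to 1 total, a requirement added after both ratios had been seen. In simulated counts edgeR recovered 74% of 2-fold changes in L1, 57% in L2 high against zero-low and 26% in L2 low against zero. These counts were drawn independently for each gene and palm, with changes of 2-fold and 4-fold only. The median size of the changes called in L2 high against zero-low was 0.83 on the log2 scale. Power in L1 for changes below 2-fold is therefore not settled. One biological explanation, fewer embryoid lines in L1 low palms than in L2 high palms, was tested only in part within an agency. In L1, embryoid lines as a continuous term gave 0 genes. So did low palms with at least 10 lines set against zero palms. L1 palms reached at most 48 lines, fewer than any L2 high palm, so these fits cannot decide. In L2, 36 genes were called between low and zero palms and 7330 between high and zero palms, with genotype following the groups.

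The difference between CTAB and InnuPREP libraries, 11198 genes, was reached by 1 of 32 exchanges of libraries within palms, the real one. The highest other gave 0. Chance is thus unlikely, though 1 of 32 is the smallest share these exchanges can give. Thinning all libraries to the smallest left 8492 genes, between the bounds set. As totals were then equal, this argues against depth as the source of those calls. Thinning also lowers power, so a part played by depth in the calls that were lost stays open. A difference in sequencing run or read length cannot be told apart from extraction, although the labels give 50 nt for both kinds of L2 library and name no run. The share of reads assigned to more than 1 gene reached 0.297% in CTAB libraries, above the L1 maximum of 0.268%, below the lowest InnuPREP library of the same palms, 0.411%, and just inside the range of all L2 InnuPREP libraries, which starts at 0.296%. No biological explanation was tested, as both libraries came from the same palm.

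High palms differed from zero palms in 7330 genes (1 of 100 splits, highest other 1) and from low palms in 5740 (1 of 100 splits), so a chance draw of single palms is unlikely for both. These splits, too, took no account of genotype or identifier series. The highest other split of high and low palms gave 3006 genes and exchanged high palm 8 for low palm 4, which kept the 7 palms with U identifiers together. The 36 genes between low and zero palms, 0.176% of those tested, were reached by 3 of 100 splits. As every zero palm and no low palm was Yangambi_A, the splits cannot tell group from genotype. The highest other split called 3.45% of genes and grouped zero palm 2 with all low palms but the Yangambi_C palm. It was singled out as the highest, and whether these palms hold a structure other than the groups was not tested. The L1 genotype comparison gave 0 genes (edgeR; 1396 at an unadjusted p below 0.05, 21 by DESeq2), the least any split can give, so the 100 of 100 splits that reached it, with a highest other of 7, decide nothing.

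The low minus zero difference between agencies was 10 genes, reached by 2 of 100 splits, with 20 in the highest other. That split again grouped zero palm 2 with low palms 1, 2, 4 and 5 of L2. The L2 zero palms are also the only Yangambi_A palms, so genotype stays open as a source of these genes. Fitted log2 differences, L2 minus L1, were 8.84 for LOC105061162, 7.27 for LOC105036497, -5.26 for LOC105060146 and -3.25 for LOC105052074. LOC105061162 and LOC105060146 had 1 and 2 counts in 1 L2 group, so their fitted values are no bounds and depend on the prior count.

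Low palm 3, Yangambi_C, stood apart from the other low palms with an axis score of 0.66, with IAA1 at 51.4 CPM against 202 to 268 CPM, and with trnY-GUA at 71.2 CPM against 119 to 131 CPM. High palm 8, Jen Avros Yangambi, had the highest values of the high group for GPAT, at 21.8 CPM against 5.78 to 12 CPM, and for LOC105058870, at 11 CPM against 0.619 to 3.7 CPM. Other high palms stood apart for IAA1 (209 CPM in high palm 3), LOC105044093 (247 CPM in high palm 5) and LOC105052784 (1170 CPM in high palm 1). Zero palm 4 stood apart for GST at 374 CPM and LOC105058870 at 236 CPM, zero palm 2 for LOC105052784 at 6.09 CPM, and low palm 6 for psbJ at 26.2 CPM. Zero palm 5 had the lowest total count of its group, 10172221 against 11947143 to 12444209.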

How the results depend on the processing

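Tests leaving out single palms outside the CTAB comparison, with quality terms (reads outside genes and the 10 most abundant genes included), without plastid genes, with the identifier as a term, with thinned CTAB counts or without scaling were chosen after seeing the data, as were the plastid lists and all their tests. L2 high against zero-low, 8113 genes, gave 6172 (embryoid lines as a continuous term) to 9346 (limma-voom) under 10 settings, 3115 with a 2-fold minimum and 1241 with genotype as a term, of which 1165 were shared. It gave 1109 with reads outside genes and the share of the 10 most abundant genes as terms, a fit in which DRM (-0.37) and trnS-GCU (-0.12) reversed, and the cause was not tested. With identifier U as a term 1 gene was called, a fit in which only 1 high palm remains to be set against zero and low. In that fit fold changes reversed for LOC105052784 (-0.43), LOC105044093 (-2.82), GLO2 (-0.36), GSK (-0.41), psbA (-0.25) and trnS-GCU (-0.34). Over 22 named genes of both agencies, direction and side of the threshold were kept in 595 tests, the call was lost in 103 and the direction reversed in these 8. L2 low against zero, 36 genes, gave 328 with DESeq2 and 16 with no filter. DESeq2 gave 21 genes for L1 genotype and 77 for the difference between agencies. The cause was not tested. CTAB against InnuPREP, paired by palm, gave 2875 genes with no palm block, since differences between palms then enter the spread. L1 plastid lists fell from 4 to 0 with an estimated correlation and to 0 with fry, and CTAB plastid lists from 6 to 0 with an estimated correlation. Leaving out 1 palm gave 7265 to 8621 genes in L2 high against zero-low, 0 to 1 in L1 and 3 to 147 in L2 low against zero. It gave 3 to 27 between agencies and 9775 to 11717 for CTAB. For L2 low against zero and between agencies, only L2 low and zero palms were left out. L1 low against zero stayed at 0 under its other settings, low palm 9 left out being the exception. Plastid medians for CTAB were 0.9 with TMM, 0.89 with RLE and 1.17 with no scaling, where the median of all genes moved from -0.03 to 0.25. The 24 product-name lists were not run, having no names to match. In L2 low against zero, simulated recovery of 26% of 2-fold changes limits what depth and palm number can show.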

Other observations

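No test in this part was chosen only after its result was seen, except the count of genes near 0. Across 20116 genes, the difference between 17 L1 zero palms and 4 L2 zero palms correlated at 0.465 (Pearson) and 0.483 (Spearman) with the CTAB minus InnuPREP difference measured in 4 other palms. The plastid share of counts was 12.1% ± 2.5 in L1 zero palms (SD, n = 17), 2.99% ± 0.81 in L2 zero palms (SD, n = 6) and 6.24% ± 1.2 in L2 CTAB libraries (SD, n = 6). A candidate explanation for part of the difference between agencies is the extraction method, for which the correlation of 0.465 passed the bound set beforehand. Read length differed between the agencies too, per the labels. Depth ran the same way in both contrasts, with mean totals of 6191034 in L1 zero and 11832903 in L2 zero palms. They were 5934010 in CTAB and 12657736 in InnuPREP libraries of the same palms. The correlation therefore cannot tell extraction from depth or sequencing run.

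One hypothesis tested was that neighbouring genes move together more in L2 than under another treatment. In EG11 gene order, 1072 of 1961 adjacent pairs of called genes, 54.7%, moved in the same direction in L2 high against zero-low, and 51.7% of 3364 pairs did so for CTAB against InnuPREP. The difference of 3 percentage points lies between the bounds set beforehand and leaves the question open. Shuffled directions gave at most 53.6% and 53.5% in 1000 shuffles.

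LOC105061162 was the 1 gene with at most 3 counts over all 6 L2 zero palms and at least 1 CPM in every high palm, and 99 other splits of these 14 palms gave none in either direction. The splits took no account of genotype, and the 6 zero palms are also the only Yangambi_A palms. Among L2 low palms it was above 1 CPM in 5 of 6 and had 0 counts in the Yangambi_C palm. In L1 it was above 1 CPM in 17 of 17 zero palms and 13 of 15 low palms, at 5.68 ± 2.57 CPM (SD, n = 17) and 5.95 ± 3.91 CPM (SD, n = 15).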
